A study of Homo sapiens with 9 samples.

How the data were processed

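Gene expression was measured by RNA-seq in 697 cells, a human pre-B acute lymphoblastic leukaemia line with the TCF3::PBX1 fusion, grown in RPMI with 10% fetal calf serum. Per the labels' protocols, cells received lentiviral control, FOXO3 or FOXO1 constructs, EGFP-positive cells were enriched by flow sorting, RNA was extracted on RNeasy columns and libraries followed a standard Illumina preparation. Whether the preparation selected poly(A) RNA or marked strand is not given in the sources used here. There were 3 groups of 3 libraries, taken from the sample titles.

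The authors deposited a table of raw gene read counts, per the file headers, which were read as estimated counts: the deposited values are whole numbers that were used as such, for 60240 genes with Ensembl identifiers. The reading as estimated counts rests on a second deposited table of normalised values, a signal in the sense of counts divided by a factor. The ratio of the tables, computed here, was a single factor per library, within 0.1%, for 94.7% of the 4789 genes with 1 annotated transcript, and for 6.98% of the 15420 genes with several. Per the submitters' processing notes DESeq was used, with no version. The aligner, counting tool, genome build and annotation are not given in the sources used here, so no coordinates are printed. A normalisation by gene and library of that form changes the level of a gene whose reads move between long and short transcripts, which raw counts do not. Names were in the table for 23164 genes, and the 37076 genes without a name held 0.0144% to 0.0859% of a library's counts. Every column of per-sample values was used.

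Total counts were 31.6 to 40.5 M per library, 33898 genes had a count in at least 1 library, and the most abundant nuclear gene, EEF1A1, took 1.51% to 2.06%. Intervals of count ratios are exact binomial (Clopper-Pearson) at 95% and cover counting error only, since reads are not independent molecules. Replicates were compared before averaging: the chi-square per degree of freedom within groups was 14.7 to 69.7 over genes with at least 20 counts in the pair, so no pair agreed within sampling noise.

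The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3; glmQLFit and glmQLFTest) on the raw table with TMM factors (0.944 to 1.044), the filterByExpr filter, which kept 18682 genes, a prior count of 2, all 9 libraries in a single fit and no covariates. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The prior count pulls the log2 fold changes of genes with few counts toward 0, so these can be smaller than the ratio of the counts. The SE of a log2 fold change is its absolute value divided by the square root of the test's F statistic. Levels are CPM, counts scaled by the TMM-adjusted library total. The comparisons were FOXO3 against control, FOXO1 against control and FOXO1 against FOXO3. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation as an alternative and fry beside it, adjusted over the 31 lists. Fry tests the list's own genes and does not compare them with other genes.

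The 31 lists (625 entries, all matched) were fixed before the data were examined, as were the tests and the rule for the genes named in the text. They were FOXO target genes, lymphocyte homing and adhesion, V(D)J recombination and light chain, pre-B receptor signalling, B lineage transcription factors, IL7 and cytokine receptors, TCF3::PBX1 associated genes, S phase and DNA replication, G2/M and mitosis, G1 cyclins with CDKs and their inhibitors, MYC and ribosome biogenesis, cytosolic ribosomal proteins, BCL2 family and apoptosis, p53 targets, autophagy and lysosome, the insulin, PI3K, AKT and mTOR pathway, sterol and fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, integrated stress and unfolded protein response, interferon response, NF-kB response, MHC class II, mature B and plasma cell, progenitor, myeloid, T cell and adherent cell markers, mitochondrially encoded transcripts, replication-dependent histones and immediate early genes. The rule named the FOXO family and, per comparison, the 10 largest rises and 10 largest falls among called protein-coding genes with a mean of at least 1 CPM in the higher group and no overlap between groups. It also took up to 4 members of smallest adjusted p per list, the 5 largest shared rises and falls, and the 5 largest opposite changes. This gave 401 results on 242 genes, of which the text prints a part, and 1 gene the rule took is not reported. Genes with near-identical copies (FOXO3, HSPA1A and HSPA1B, histones, metallothioneins, MHC class II) can share reads.

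The gene tests and camera were tried on simulated counts drawn from the real means and library sizes with 200 changed genes among 18682. The other steps were not tried this way. For FOXO3 against control, edgeR recovered 28.4%, 55.2% and 81.8% of genes changed 1.5-fold, 2-fold and 4-fold, with 13 unchanged genes called (10.6% of calls). For FOXO1 against control it recovered 17.9%, 65.7% and 89.4%, with 10 such calls (8.0%). With DESeq2 unchanged genes made up 23.4% and 17.5% of calls. Camera called the shifted list and 0 of 25 unshifted lists in each. Simulated genes were drawn independently, so this does not test camera at the preset correlation on lists whose genes vary together.

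Samples of different groups share replicate numbers. For FOXO3 and FOXO1 libraries with the same number, deviations from the group means correlated at 0.173, 0.129 and 0.243, each above 0.1, so the numbers were taken to pair these samples. Control replicate 2 correlated at 0.312 with FOXO1 replicate 3 and at 0.177 with FOXO3 replicate 3, which do not share its number. A value above 0.1 therefore does not by itself mark a pair, and the pairing is an assumption. The main test, fixed before the data were examined, left this pairing out. The labels do not say what a number stands for. Alternatives tried were edgeR's RLE factors, library totals, no filter, a minimum mean of 1 CPM, DESeq2 1.42.0, limma voom, limma-trend on log2 of the deposited normalised value with a pseudocount of 1, a fit of the 6 compared samples, a replicate block, removal of FOXO1, FOXO3 and their copies, and each library left out in turn. Added after seeing the data were a fit with the deposited factors as offsets, removal of the unnamed gene as well, and a fit of 6 samples with the block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.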

Results

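RNA was profiled in 697 cells, an established human pre-B acute lymphoblastic leukaemia line that carries the TCF3::PBX1 fusion. The cells had been transduced with a lentiviral vector that carried no added factor (control), the FOXO3 cDNA or the FOXO1 cDNA, and cells positive for the vector's EGFP reporter were enriched by sorting. FOXO3 and FOXO1 are forkhead transcription factors that PI3K and AKT signalling keeps out of the nucleus. Each group held 3 libraries, 9 in all. The total estimated count per library was 39.4 ± 0.969 M in control, 34.6 ± 2.89 M in FOXO3 and 36.4 ± 0.516 M in FOXO1 (SD, n = 3), and ran from 31.6 to 40.5 M. Transcripts encoded by mitochondrial DNA took 5.81% to 7.77% of a library's counts. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The libraries separated by construct: the first principal component held 44.5% of the variance and the second 21.2%. Log expression correlated at 0.982 to 0.990 within groups and at 0.953 to 0.974 between groups, across genes, which are not independent replicates.

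**Figure D1:**
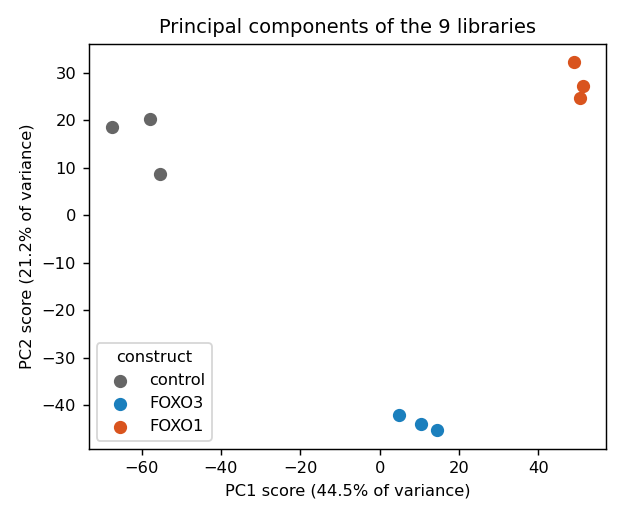
Scores of the 9 libraries on the first principal component (horizontal axis, 44.5% of variance) and the second (vertical axis, 21.2%), 1 point per library, coloured by construct. The 3 control libraries lie between -67.4 and -55.2 on the first component and the 3 FOXO1 libraries between 48.9 and 51.2, with the FOXO3 libraries between 4.78 and 14.5.

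The levels of the introduced genes were examined first. FOXO3 (ENSG00000118689) had 49920 to 59145 counts per library with its construct, against 1380 to 1616 in control and 1190 to 1360 in FOXO1 libraries. It was 39.2-fold higher in FOXO3 than in control libraries (log2 fold change 5.29, SE 0.11, adjusted p = 9.52e-10). FOXO1 (ENSG00000150907) had 3944 to 5039 counts per library with its construct, against 1575 to 2247 in control and 1159 to 1303 in FOXO3 libraries, a 2.52-fold rise (log2 fold change 1.33, SE 0.14, adjusted p = 5.58e-05). On the values that the authors normalised, the same FOXO1 comparison was 45472 ± 3721 against 685 ± 159.5 (SD, n = 3), a ratio of 66.3, and the FOXO3 ratio was 102. The gap between the raw and the normalised ratio arises in the deposited factor of each gene and library. A gene with an identifier and no symbol, ENSG00000288542, held 21743 to 23878 counts in each FOXO1 library, 0 to 28 in control and 0 to 57 in FOXO3 libraries. Counted together with it, FOXO1 was 15.1 times its control level. FOXO3 shares near-identical sequence with FOXO3B, so reads of the pair can be split between them. FOXO3B had 408 to 549 counts in FOXO3 libraries and 493 to 617 in control, which argues against many construct reads being counted there.

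Levels of the other family members also differed. FOXO4 rose with FOXO3 (log2 fold change 0.76, SE 0.13, adjusted p = 0.00167) and fell with FOXO1 (-0.53, SE 0.13, adjusted p = 0.00874), although the fall was lost on the deposited normalised values (adjusted p = 0.197) and with the deposited factors as offsets (adjusted p = 0.187; log2 fold change -0.33 in both). FOXO6 fell with FOXO1 (log2 fold change -1.01, SE 0.17, adjusted p = 0.00103). Its fall with FOXO3 (-0.60, SE 0.17, adjusted p = 0.0213) was lost without FOXO3 replicate 1 (adjusted p = 0.0649) or FOXO3 replicate 3 (adjusted p = 0.0621). FOXO1 was lower in FOXO3 than in control libraries (log2 fold change -0.42, SE 0.14, adjusted p = 0.0457). That call was lost without control replicate 3 (adjusted p = 0.166), FOXO3 replicate 1 (0.0765), 2 (0.0835) or 3 (0.0877) or FOXO1 replicate 1 (0.0515), and under library totals, limma voom and both uses of the deposited factors. The log2 fold change was -0.24 without control replicate 3, -1.04 on the deposited normalised values and -0.89 with the deposited factors as offsets. FOXO3 in FOXO1 libraries did not pass the test (log2 fold change -0.24, SE 0.09, adjusted p = 0.0562), and passed it without control replicate 1 (adjusted p = 0.0248) and with DESeq2 (adjusted p = 0.0316).

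**Figure D2:**
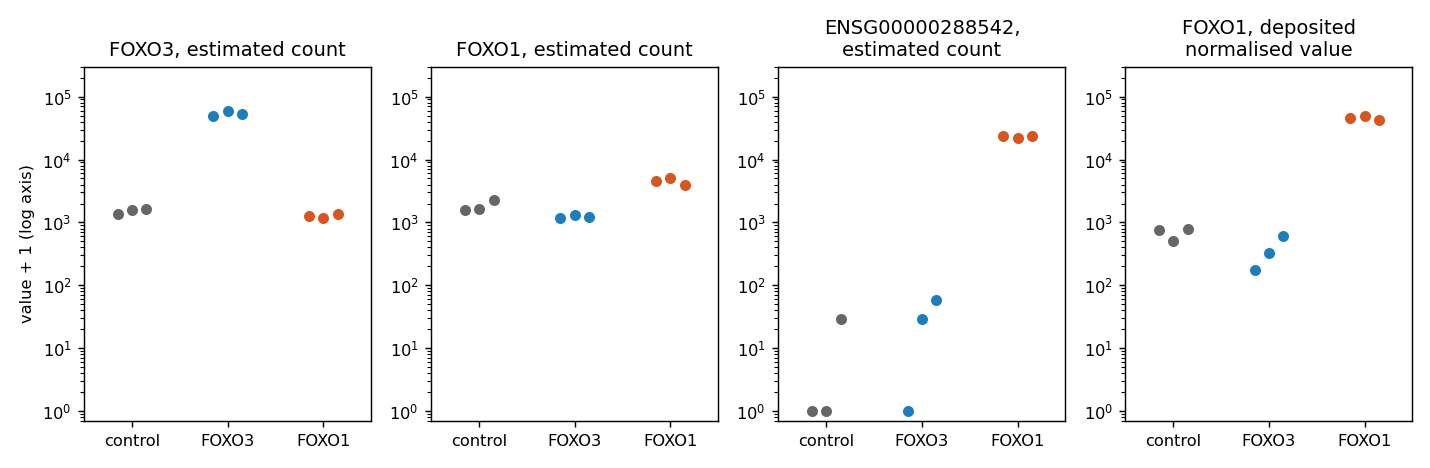
Values of FOXO3, FOXO1 and ENSG00000288542 in each library plus 1, on a log axis, 1 point per library, with the construct on the horizontal axis. The left 3 panels show estimated counts and the right panel the deposited normalised value of FOXO1, whose FOXO1 libraries lie at 41924 to 49344.

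The first comparison asked which transcripts forced expression of FOXO3 changed against the control vector. By camera with a preset correlation, the lists for lymphocyte homing, V(D)J recombination, MHC class II, interferon response and replication-dependent histones were called higher. Those for sterol and fatty acid synthesis, DNA replication, ribosome biogenesis and oxidative phosphorylation were called lower. With an estimated correlation the lowest adjusted p of any list was 0.0806. The largest rises included SELENOP, which encodes a selenium transport protein, at 45.0 ± 4.67 CPM (counts scaled by TMM-adjusted library totals) with FOXO3 against 0.289 ± 0.0322 in control (SD, n = 3; log2 fold change 7.04, SE 0.19, adjusted p = 1.26e-08). GIMAP4, an immunity-associated GTPase, had 739 counts over the FOXO3 libraries against 2 over the control libraries, a ratio of 421 with a 95% counting interval of 116 to 3484 (log2 fold change 6.67, SE 0.41, adjusted p = 3.05e-06). The fitted change, 102-fold, lies below that interval because the prior count pulls it toward 0. The collagen gene COL5A3 (38.3-fold), the protease HTRA3 (35.7-fold), the transporter SLC16A11 (32.4-fold), TMEM204 (32.4-fold), FGFBP2 (27.0-fold), the guanylate binding protein GBP2 (23.7-fold) and the hormone prolactin, PRL (23.5-fold), rose too, with adjusted p between 1.69e-07 and 5.86e-06.

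With FOXO3, RGS1, a regulator of G protein signalling, fell 4.59-fold (log2 fold change -2.20, SE 0.37, adjusted p = 0.00165), and the prostaglandin receptor PTGER4 (4.52-fold), the serotonin receptor HTR7 (4.50-fold), C6orf223 (4.29-fold), the DNA demethylase TET1 (4.06-fold) and the adaptor PAG1 (3.94-fold) fell with adjusted p between 0.000161 and 0.00608. The heat shock genes HSPA6 (log2 fold change -4.76, SE 1.03, adjusted p = 0.00581) and HSPA1A (-4.48, SE 1.08, adjusted p = 0.0101) had the largest fitted falls. Control replicate 1 stood apart for these genes: HSPA6 was 12.3 CPM there against 0.695 and 1.54 in the other controls, and HSPA1A 9.76 against 0.334 and 1.89. Without control replicate 1 their log2 fold changes were -2.72 and -2.70. C6orf223 had -1.49 without control replicate 2. The HSPA6 and HSPA1A calls were lost with limma voom (adjusted p = 0.0563 and 0.0962). The glycine transporter SLC6A9 (-2.39, SE 0.82, adjusted p = 0.0472) had 18.9 CPM in control replicate 1 against 1.98 and 5.03, and its call was lost with limma voom, under library totals, with both uses of the deposited factors, and without control replicate 1 (log2 fold change -1.13, adjusted p = 0.24), control replicate 3 (0.0671) or FOXO3 replicate 1 (0.122), 2 (0.1) or 3 (0.114). The hypoxia-responsive ANKRD37 (-2.11, SE 0.70, adjusted p = 0.0422) was at 21.8 CPM in control replicate 2 and lost its call without control replicate 2 (adjusted p = 0.137), control replicate 3 (0.0583), FOXO3 replicate 1 (0.129) or FOXO3 replicate 3 (0.11).

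Among the fixed gene lists, FOXO target genes moved upward as a group with FOXO3: 12 of 26 tested members rose and 4 fell (13 and 4 adjusted over the list alone) (camera adjusted p = 8.06e-07, adjusted p = 0.137 with an estimated correlation). DEPP1, an autophagy regulator, rose 14.2-fold (log2 fold change 3.83, SE 0.14, adjusted p = 1.05e-07), the PI3K inhibitor PIK3IP1 9.56-fold, the death ligand TNFSF10 5.33-fold and the sestrin SESN3 3.81-fold. Of lymphocyte homing and adhesion genes, 7 of 13 tested members rose and 1 fell (7 and 1 adjusted over the list alone) (camera adjusted p = 0.000143, adjusted p = 0.0806 with an estimated correlation). L-selectin, SELL, rose to 41.5 ± 8.93 CPM from 5.63 ± 0.268 (log2 fold change 2.87, SE 0.15, adjusted p = 1.2e-06), and the egress receptor S1PR1 (2.32) and the chemokine receptor CCR7 (0.99) rose on the log2 scale too. In the V(D)J recombination and light chain list 7 of 15 tested members rose and 1 fell (8 and 1 adjusted over the list alone) (camera adjusted p = 0.000119, adjusted p = 0.137 with an estimated correlation). The recombinase gene RAG1 rose 4.14-fold (log2 fold change 2.05, SE 0.14, adjusted p = 5.45e-06) and RAG2 by 1.32 on the log2 scale. Of B lineage transcription factors, 7 of 25 tested members rose and 1 fell (8 and 1 adjusted over the list alone) (camera adjusted p = 0.00821, adjusted p = 0.224 with an estimated correlation), led by SPIB (4.86-fold), TCF4 (3.47-fold) and ERG (2.38-fold). Of genes associated with TCF3::PBX1, 5 of 8 tested members rose (6 adjusted over the list alone) (camera adjusted p = 0.000119, adjusted p = 0.0806 with an estimated correlation). The receptor tyrosine kinase MERTK rose 3.86-fold (log2 fold change 1.95, SE 0.11, adjusted p = 1.63e-06). The call of ROR1 was lost without control replicate 2 (adjusted p = 0.0577) or FOXO3 replicate 3 (0.0732). PBX1 counts can hold reads of the fusion transcript as well.

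Antigen presentation and interferon lists also rose. Of MHC class II genes, 8 of 11 tested members rose (9 adjusted over the list alone) (camera adjusted p = 7.52e-05, adjusted p = 0.436 with an estimated correlation), among them HLA-DMA (log2 fold change 1.42, SE 0.11, adjusted p = 1.38e-05), HLA-DOA (1.93) and the transactivator CIITA (0.88). Of the interferon response list, 9 of 20 tested members rose and 1 fell (10 and 1 adjusted over the list alone) (camera adjusted p = 0.00967, adjusted p = 0.137 with an estimated correlation). IFIT3 rose by 1.71 and IFIT2 by 2.18 on the log2 scale. Of replication-dependent histone genes, whose transcripts end in a stem-loop and lack a poly(A) tail, 11 of 15 tested members rose (13 adjusted over the list alone) (camera adjusted p = 1.37e-08, adjusted p = 0.224 with an estimated correlation). H4C8 rose 4.01-fold and H2AC6 3.01-fold, and reads of near-identical histone genes can be split between them. In the insulin, PI3K, AKT and mTOR pathway list 11 of 26 tested members rose and 4 fell (11 and 4 adjusted over the list alone) (camera adjusted p = 0.00939, adjusted p = 0.224 with an estimated correlation), among them the mTORC1 inhibitor TSC1 (log2 fold change 1.09, SE 0.09, adjusted p = 1.88e-05) and the receptor IGF1R (1.24). The list's call was lost without control replicate 2 (adjusted p = 0.0507), on the deposited normalised values (0.201) and with the deposited factors as offsets (0.056).

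Biosynthetic and cell cycle lists fell with FOXO3. Of sterol and fatty acid synthesis genes, 20 of 20 tested members fell (20 adjusted over the list alone), with a mean log2 fold change of -1.04 (camera adjusted p = 5.65e-10, adjusted p = 0.267 with an estimated correlation). SQLE, a rate-limiting sterol enzyme, was 84.3 ± 19.8 CPM with FOXO3 against 223 ± 52.5 in control (SD, n = 3; log2 fold change -1.41, SE 0.20, adjusted p = 0.000506), and INSIG1, CYP51A1 and DHCR7 fell 2.56-fold, 2.72-fold and 3.05-fold. Of S phase and DNA replication genes, 21 of 25 tested members fell (24 adjusted over the list alone) (camera adjusted p = 1.6e-09, adjusted p = 0.359 with an estimated correlation). The phosphatase CDC25A fell 2.05-fold (log2 fold change -1.03, SE 0.13, adjusted p = 0.000251) and cyclin E1, CCNE1, 2.19-fold. Of G2/M and mitosis genes, 10 of 25 tested members fell (18 adjusted over the list alone) (camera adjusted p = 4.11e-05, adjusted p = 0.535 with an estimated correlation), among them CCNA2 (-0.77) and CCNB1 (-0.55). In the MYC and ribosome biogenesis list 1 of 25 tested members rose and 16 fell (1 and 16 adjusted over the list alone) (camera adjusted p = 2.1e-05, adjusted p = 0.4 with an estimated correlation). The nucleolar proteins NOP58 (-0.74), WDR12 (-0.98) and FBL (-0.63) fell, and ODC1, the rate-limiting enzyme of polyamine synthesis, rose (log2 fold change 2.20, SE 0.18, adjusted p = 1.66e-05). Of nuclear-encoded oxidative phosphorylation genes, 13 of 22 tested members fell (13 adjusted over the list alone) (camera adjusted p = 0.00106, adjusted p = 0.481 with an estimated correlation), including the mitochondrial transcription factor TFAM (-0.59).

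For glycolysis and hypoxia genes, 1 of 22 tested members rose and 8 fell (1 and 11 adjusted over the list alone) (camera adjusted p = 0.00489, adjusted p = 0.631 with an estimated correlation). The aldolase ALDOC fell (log2 fold change -1.44, SE 0.20, adjusted p = 0.000586) and PFKL rose (0.98). Control replicate 2 and FOXO1 replicate 3 had high levels of ANKRD37, a member of this list (21.8 and 20.1 CPM). Of integrated stress and unfolded protein response genes, 8 of 20 tested members fell (8 adjusted over the list alone) (camera adjusted p = 0.000871, adjusted p = 0.535 with an estimated correlation), among them DNAJB9 (-1.11) and ATF3 (-1.70). Control replicate 1 stood apart for heat shock genes, as given above. Without it the median of the stress response list went from -0.82 to -0.40 (camera adjusted p = 0.0212).

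Other lists were not called with FOXO3. Among cyclins, CDKs and CDK inhibitors of G1, 2 of 17 tested members rose and 6 fell (2 and 7 adjusted over the list alone) (adjusted p = 0.265): the CDK inhibitor CDKN1B rose 1.78-fold and CDK4 and CDKN1A fell 1.99-fold and 1.84-fold. In the BCL2 family and apoptosis list 4 of 24 tested members rose and 4 fell (5 and 4 adjusted over the list alone) (adjusted p = 0.527). The BH3-only genes BMF (log2 fold change 2.44, SE 0.12, adjusted p = 6.44e-07) and HRK (1.12) rose, the anti-apoptotic BCL2 fell (-0.96), and the BH3-only gene BIK had 60 counts with FOXO3 against 3 in control, a ratio of 22.8 with a 95% counting interval of 7.44 to 114. For p53 targets 4 of 21 tested members rose and 3 fell (4 and 3 adjusted over the list alone) (adjusted p = 0.44), the median being -0.12 while the mean and the test pointed up; TP53INP1 (2.24) and SESN1 (1.70) rose. Pre-B receptor signalling genes went both ways (6 of 23 tested members rose and 4 fell (7 and 5 adjusted over the list alone); adjusted p = 0.527), CD72 rising 3.25-fold. For IL7 and cytokine receptor genes, 8 of 21 tested members rose and 3 fell (8 and 3 adjusted over the list alone) (adjusted p = 0.132), with rises of CSF2RB (1.62) and JAK1 (1.37) and falls of FLT3 (-0.63) and IL21R (-1.51), and DESeq2 called the list higher (adjusted p = 0.0399). Of autophagy and lysosome genes, 6 of 22 tested members rose and 1 fell (7 and 1 adjusted over the list alone) (adjusted p = 0.44), MAP1LC3B and GABARAPL2 rising by 0.48 and 0.55 on the log2 scale. The NF-kB response list had 3 rises among 13 tested members (3 adjusted over the list alone; adjusted p = 0.527), including NFKB1 (0.55). In the immediate early genes 3 of 17 tested members rose and 2 fell (3 and 2 adjusted over the list alone) (adjusted p = 0.627), ZFP36 rising (0.71) and JUN falling (-1.62). Cytosolic ribosomal proteins had 1 fall, RPL5 (-0.28), among 26 tested members (0 adjusted over the list alone; adjusted p = 0.231), and the list was called lower without control replicate 2 (adjusted p = 0.00454). The call of RPL5 was lost without control replicate 1 (adjusted p = 0.0656), 3 (0.136), FOXO3 replicate 1 (0.0592), 2 (0.088), 3 (0.089) or FOXO1 replicate 1 (0.0564), and under library totals, with no filter, under a minimum mean of 1 CPM and in a fit of the 6 compared samples.

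Marker lists of other stages and cell types were not called with FOXO3. Mature B and plasma cell markers went both ways (4 of 12 tested members rose and 4 fell (4 and 4 adjusted over the list alone); adjusted p = 0.627), the median being -0.10 while the mean and the test pointed up; the plasma cell regulator PRDM1 rose (log2 fold change 2.46, SE 0.17, adjusted p = 7.23e-06), as did CD38 (1.13) and CD27 (1.55). Of progenitor markers, 1 of 6 tested members rose and 1 fell (2 and 1 adjusted over the list alone) (adjusted p = 0.187), the endopeptidase MME, known as CD10, rising (log2 fold change 2.26, SE 0.12, adjusted p = 1.21e-06). T cell markers had 3 rises and 2 falls among 10 (4 and 2 adjusted over the list alone; adjusted p = 0.687), the kinase LCK falling (-0.99). Adherent cell markers had 1 rise, TAGLN (0.77), and 1 fall, CDH2 (-0.31), among 6 (1 and 1 adjusted over the list alone; adjusted p = 0.527). The call of CDH2 was lost without control replicate 2 (adjusted p = 0.0629), 3 (0.0683), FOXO3 replicate 1 (0.0616) or 2 (0.0634), and under library totals, with no filter, on the deposited normalised values and with the deposited factors as offsets. By edgeR, 0 of 7 myeloid markers and 0 of 15 mitochondrially encoded transcripts passed, with 0 at an unadjusted p under 0.05 and 0 by DESeq2, limma voom and limma-trend in each list; CEBPA had log2 fold change -0.56, SE 0.26, adjusted p = 0.133 and MT-CO1 0.10, SE 0.12, adjusted p = 0.551. CEBPA passed with the replicate block (adjusted p = 0.0455) and CEBPB without control replicate 2 (0.0152).

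Across all genes, edgeR's quasi-likelihood test called 5858 of 18682 tested genes in FOXO3 against control at an adjusted p under 0.05, 2979 higher and 2879 lower. The balance turned with the scaling or tool: 3180 were higher and 2459 lower under library totals, 2867 and 3014 with RLE factors and 2754 and 3412 with DESeq2. More than 2-fold, 1209 were higher and 261 lower. The libraries of the groups did not overlap for 44.4% of tested genes, where chance gives 10%. Of the 31 lists, 16 were called with the preset correlation. Fry, which tests whether a list's genes move one way on balance, called 22. It did not call glycolysis and hypoxia (adjusted p = 0.139) or the integrated stress list (0.0755), both called by camera.

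**Figure D3:**
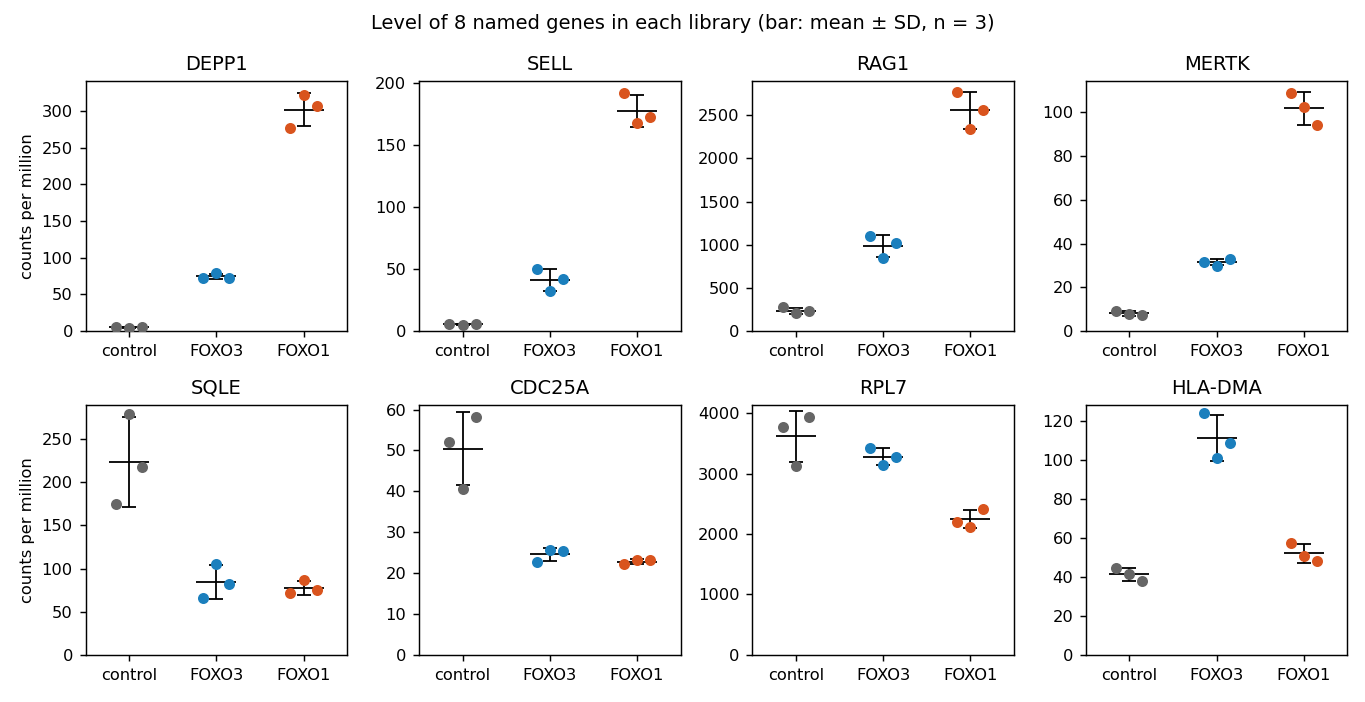
Level of 8 genes in each library in CPM (vertical axis, from 0) by construct (horizontal axis), 1 point per library, with bars for the mean ± SD (n = 3). DEPP1, SELL, RAG1 and MERTK were highest with FOXO1, SQLE and CDC25A were lower with both constructs than in control, RPL7 was lowest with FOXO1 and HLA-DMA highest with FOXO3.

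The second comparison asked the same of FOXO1. By camera with the preset correlation, the homing, V(D)J recombination, TCF3::PBX1-associated, histone and progenitor marker lists were called higher. The sterol synthesis, DNA replication, ribosome biogenesis, ribosomal protein and oxidative phosphorylation lists were called lower. The TCF3::PBX1 list alone was also called with an estimated correlation (adjusted p = 0.0421). The largest rises reported here included the metallothionein MT1M, at 34.4 ± 4.70 CPM with FOXO1 against 0.235 ± 0.0739 in control (SD, n = 3; log2 fold change 6.89, SE 0.24, adjusted p = 4.36e-08). Its reads can be shared with other metallothionein genes. The phospholipid flippase ATP9A rose 99.7-fold (log2 fold change 6.64, SE 0.22, adjusted p = 2.78e-08), PRL 77.0-fold, the transcription factor CREB3L1 63.3-fold, DEPP1 57.6-fold, GGACT 52.8-fold and CD247, the T cell receptor zeta chain, 46.3-fold, with adjusted p between 9.29e-09 and 6.51e-07. GIMAP4 had 699 counts over the FOXO1 libraries against 2 in control, a ratio of 378 with a 95% counting interval of 104 to 3130. BIK had 665 against 3, a ratio of 239.9 with an interval of 81.7 to 1166 (log2 fold change 6.20, SE 0.32, adjusted p = 4.6e-07). The fitted change of BIK, pulled toward 0 by the prior count, also lies below its interval. The cytokine receptor IL9R fell (log2 fold change -3.58, SE 0.31, adjusted p = 1.18e-05), and MS4A1, which encodes CD20, 11.6-fold (-3.53, SE 0.26, adjusted p = 3.8e-06). NKAIN4, SCG2, RGS1, SLC14A1, SH3BGR, PDZRN4, FSTL4 and TET1 fell between 8.40-fold (TET1) and 10.3-fold (NKAIN4).

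The homing list rose with FOXO1: 7 of 13 tested members rose and 3 fell (8 and 3 adjusted over the list alone) (camera adjusted p = 4.23e-05, adjusted p = 0.054 with an estimated correlation). SELL reached 178 ± 13.0 CPM (log2 fold change 4.96, SE 0.17, adjusted p = 3.16e-08), S1PR1 rose 10.9-fold and CCR7 4.04-fold, while the integrin ITGB7 fell 8.14-fold. In the V(D)J recombination and light chain list 10 of 15 tested members rose and 2 fell (10 and 2 adjusted over the list alone) (camera adjusted p = 4.48e-06, adjusted p = 0.0834 with an estimated correlation). RAG1 rose 10.7-fold to 2556 ± 211 CPM (log2 fold change 3.42, SE 0.14, adjusted p = 1.56e-07) and RAG2 2.97-fold. Of B lineage transcription factors, 12 of 25 tested members rose and 4 fell (12 and 4 adjusted over the list alone) (camera adjusted p = 0.00121, adjusted p = 0.164 with an estimated correlation). ERG (2.55), TCF4 (2.12), IRF4 (1.40) and BACH2 (0.99) rose, and the list's call was lost on the deposited normalised values (adjusted p = 0.0876). Of TCF3::PBX1-associated genes, 6 of 8 tested members rose (6 adjusted over the list alone) (camera adjusted p = 4.38e-07, adjusted p = 0.0421 with an estimated correlation). MERTK rose 12.5-fold (log2 fold change 3.64, SE 0.12, adjusted p = 2.62e-08), and ANKS1B (1.10), PBX1 (1.17) and BMI1 (0.70) rose on the log2 scale. Of progenitor markers, 4 of 6 tested members rose and 1 fell (4 and 1 adjusted over the list alone) (camera adjusted p = 0.00168, adjusted p = 0.1 with an estimated correlation). MME (2.84), LMO2 (1.58) and KIT (2.63) rose and FLT3 fell (-0.76). That call was lost with limma voom (adjusted p = 0.0904) and on the deposited normalised values (0.0876).

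FOXO target genes went both ways with FOXO1: 8 of 26 tested members rose and 4 fell (9 and 5 adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.0228, adjusted p = 0.413 with an estimated correlation). The median was -0.11, 0.13 and 0.11 without control replicate 1, 2 and 3, and 0.18, 0.10 and -0.14 without FOXO1 replicate 1, 2 and 3. DEPP1 rose to 302 ± 22.8 CPM (log2 fold change 5.85, SE 0.15, adjusted p = 9.29e-09), and KLF2, a regulator of lymphocyte trafficking (4.74), CITED2 (1.08) and GADD45A (1.49) rose. The list's call was lost without FOXO1 replicate 3 (adjusted p = 0.0856), with limma voom (0.345) and on the deposited normalised values (0.308). Of replication-dependent histones, 10 of 15 tested members rose (10 adjusted over the list alone) (camera adjusted p = 0.000392, adjusted p = 0.468 with an estimated correlation), H4C8 rising 3.14-fold.

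Sterol and fatty acid synthesis genes fell with FOXO1 as a group: 19 of 20 tested members fell (20 adjusted over the list alone) (camera adjusted p = 1.84e-08, adjusted p = 0.412 with an estimated correlation). DHCR7 (log2 fold change -2.04, SE 0.25, adjusted p = 0.000139), SQLE (-1.52), CYP51A1 (-1.59) and HMGCS1 (-2.02) were lower. Of S phase and DNA replication genes, 19 of 25 tested members fell (21 adjusted over the list alone) (camera adjusted p = 4.38e-07, adjusted p = 0.468 with an estimated correlation). CDC25A fell 2.21-fold (log2 fold change -1.14, SE 0.13, adjusted p = 7.51e-05) and the helicase subunits MCM2, MCM4 and MCM6 1.98-fold, 2.14-fold and 2.06-fold. Of G2/M and mitosis genes, 16 of 25 tested members fell (22 adjusted over the list alone) (camera adjusted p = 0.00043, adjusted p = 0.652 with an estimated correlation), including AURKA (-0.70) and CCNB1 (-0.72). In the MYC and ribosome biogenesis list 18 of 25 tested members fell (21 adjusted over the list alone), and 1 rose only when adjusted over the list alone, ODC1 (camera adjusted p = 3.31e-08, adjusted p = 0.412 with an estimated correlation). FBL (log2 fold change -1.18, SE 0.10, adjusted p = 1.35e-05), NPM1 (2.00-fold) and PES1 (-1.02) fell. Of cytosolic ribosomal proteins, 21 of 26 tested members fell (23 adjusted over the list alone) (camera adjusted p = 6.77e-07, adjusted p = 0.539 with an estimated correlation). RPL5 fell 1.68-fold (log2 fold change -0.75, SE 0.10, adjusted p = 0.000203) and RPS6 1.62-fold. Of nuclear-encoded oxidative phosphorylation genes, 17 of 22 tested members fell (19 adjusted over the list alone) (camera adjusted p = 2.76e-05, adjusted p = 0.413 with an estimated correlation), among them ATP5PB (-0.70), CYC1 (-0.75) and SDHB (-0.62). Of integrated stress and unfolded protein response genes, 6 of 20 tested members fell (4 adjusted over the list alone) (camera adjusted p = 0.0408, adjusted p = 0.708 with an estimated correlation), ATF3 falling (-1.51). That call was lost without control replicate 1 (adjusted p = 0.253), the library with high heat shock transcripts, without FOXO1 replicate 2 (0.0955) or 3 (0.0962), and under a minimum mean of 1 CPM (0.124).

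Lists that were not called with FOXO1 still held called genes. In the BCL2 family and apoptosis list 5 of 24 tested members rose and 6 fell (5 and 6 adjusted over the list alone) (adjusted p = 0.228), the median being -0.01 while the mean and the test pointed up; BMF (log2 fold change 2.73, SE 0.12, adjusted p = 1.7e-07) and HRK (2.08) rose and the death receptor FAS fell (-1.64). Among cyclins, CDKs and CDK inhibitors of G1, 5 of 17 tested members rose and 7 fell (5 and 7 adjusted over the list alone) (adjusted p = 0.61), CDKN2D (1.14) and CDKN1B (0.62) rising and CDK4 (-0.97) and CDKN1A (-1.23) falling. For p53 targets 3 of 21 tested members rose and 8 fell (3 and 8 adjusted over the list alone) (adjusted p = 0.44), with BTG2 (2.02) among the rises. Pre-B receptor signalling genes went both ways (6 of 23 tested members rose and 7 fell (7 and 8 adjusted over the list alone); adjusted p = 0.58): the phosphatase PTPRC, known as CD45, fell 7.98-fold (log2 fold change -3.00, SE 0.13, adjusted p = 1.7e-07), CD22 fell (-1.01) and CD19 (0.98) and CD24 (0.69) rose. For IL7 and cytokine receptors, 9 of 21 tested members rose and 3 fell (9 and 3 adjusted over the list alone) (adjusted p = 0.108), JAK1 (1.45) and SOCS2 (1.56) rising, and the list was called higher with no filter (adjusted p = 0.0344). In the interferon response list 6 of 20 tested members rose and 8 fell (6 and 8 adjusted over the list alone) (adjusted p = 0.57), OAS2 (-0.89) and IFI44 (-1.47) falling and IRF7 rising (1.33). Of MHC class II genes, 2 of 11 tested members rose and 4 fell (2 and 4 adjusted over the list alone) (adjusted p = 0.184), CIITA rising (0.87) and HLA-DPA1 falling (-1.30), and the list was called lower without FOXO1 replicate 1 (adjusted p = 0.0373), with the replicate block (0.0247) and with no filter (0.0309). For glycolysis and hypoxia, 1 of 22 tested members rose and 4 fell (1 and 4 adjusted over the list alone) (adjusted p = 0.0917), GPI falling (-0.84). This list was called lower without control replicate 1 (adjusted p = 0.0277) and without FOXO1 replicate 3 (0.000801), which had high ANKRD37. It was also called lower with the replicate block (adjusted p = 0.0272), limma voom (0.046) and no filter (0.013).

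In the insulin, PI3K, AKT and mTOR list 11 of 26 tested members rose and 7 fell (12 and 7 adjusted over the list alone) (adjusted p = 0.558), IRS1 rising (1.37) and MTOR falling (-1.18). Autophagy and lysosome genes had 2 rises and 1 fall among 22 (2 and 1 adjusted over the list alone; adjusted p = 0.821), ULK2 falling (-1.48). The NF-kB response list (4 of 13 tested members rose and 2 fell (4 and 2 adjusted over the list alone); adjusted p = 0.558) included rises of NFKBIA (0.84) and ICAM1 (1.96). Among immediate early genes 3 of 17 tested members rose and 2 fell (3 and 1 adjusted over the list alone) (adjusted p = 0.889). The median and mean were below 0 while the test pointed up, and MYC fell 3.46-fold (log2 fold change -1.79, SE 0.32, adjusted p = 0.0014). Mature B and plasma cell markers had 7 falls and 2 rises among 12 (7 and 2 adjusted over the list alone; adjusted p = 0.169), PRDM1 rising 5.03-fold, and were called lower with no filter (adjusted p = 0.0152). T cell markers (3 of 10 tested members rose and 5 fell (3 and 5 adjusted over the list alone); adjusted p = 0.229) included a fall of TRAC (log2 fold change -2.96, SE 0.30, adjusted p = 4.06e-05). Myeloid markers had 1 rise, LYZ (0.92), and 1 fall, CSF1R (-1.58, lost on the deposited normalised values with adjusted p = 0.0614), among 7 (1 and 1 adjusted over the list alone; adjusted p = 0.821). Of adherent cell markers and mitochondrially encoded transcripts, 1 of 6 fell, COL1A1 (-0.38), and 1 of 15 rose, MT-RNR1 (0.42), with 0 and 0 adjusted over the list alone (adjusted p = 0.821 and 0.658 for the lists). The COL1A1 call was lost without control replicate 1 (adjusted p = 0.0808), 2 (0.0779), 3 (0.0504), FOXO3 replicate 1 (0.0502), 3 (0.0504), FOXO1 replicate 1 (0.0956) or 3 (0.132), and under library totals, with no filter, under a minimum mean of 1 CPM, on the deposited normalised values, in a fit of the 6 compared samples and with the deposited factors as offsets. That of MT-RNR1 was lost without control replicate 2 (adjusted p = 0.0876), 3 (0.141), FOXO3 replicate 1 (0.061), 2 (0.0644), 3 (0.0653), FOXO1 replicate 1 (0.0514) or 3 (0.144), and on the deposited normalised values, in a fit of the 6 compared samples and with the deposited factors as offsets, its log2 fold change being 0.24 without FOXO1 replicate 3.

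In FOXO1 against control, 7046 of 18682 genes were called, 3315 higher and 3731 lower, with 1483 and 742 of them past 2-fold. Scaled by library totals alone, which moved the median of all genes to 0.118 on the log2 scale, 4074 were higher and 2852 lower, and the calls of all 31 lists stayed as they were. Camera compares a list with the other genes, so a rescaling of whole libraries could hardly have changed the list calls. Non-overlapping groups made up 48.2% of tested genes against 10% by chance. With the preset correlation 14 lists were called, with an estimated correlation 1, and by fry 22. The integrated stress list, called by camera, was not called by fry (adjusted p = 0.139).

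**Figure D4:**
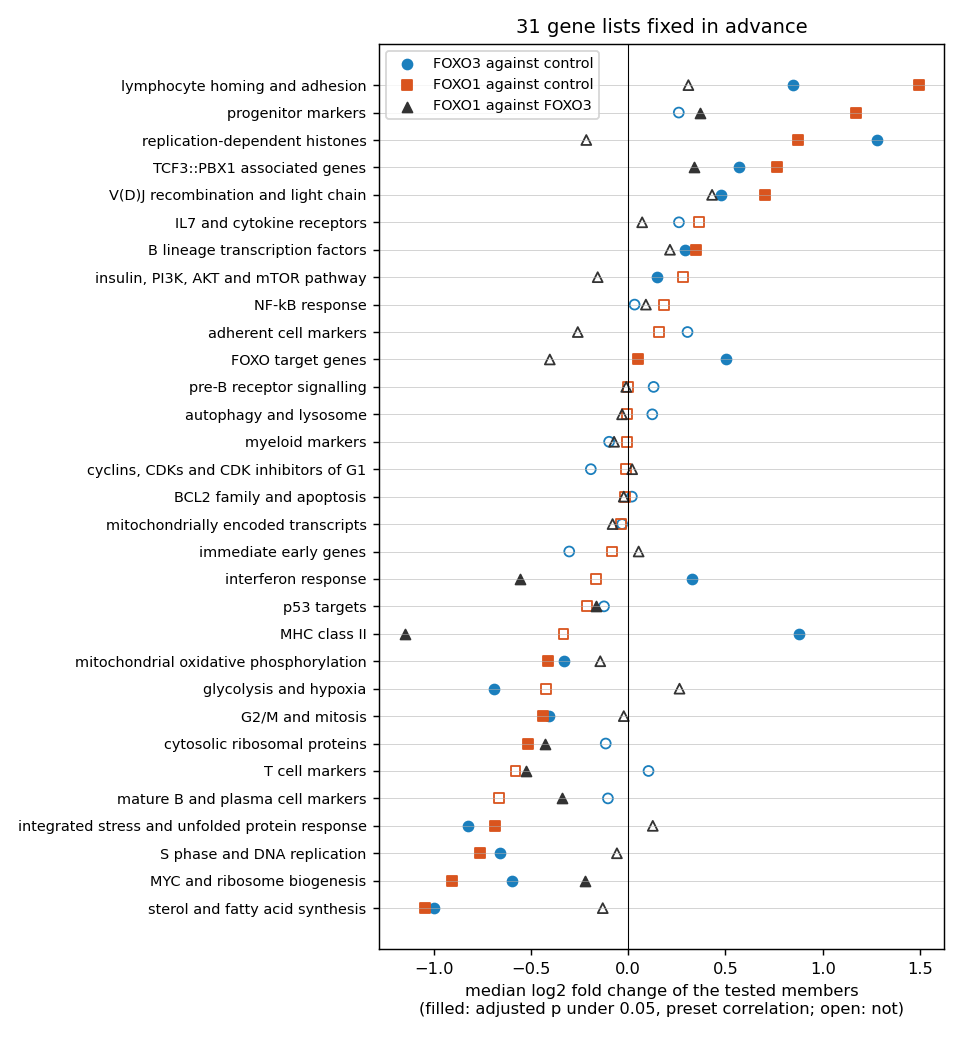
Median log2 fold change (horizontal axis) of the tested members of each of the 31 gene lists (vertical axis), with 1 marker per comparison, filled where the list's adjusted p with the preset correlation was under 0.05. Sterol synthesis genes lie at -1.04 with FOXO1, and MHC class II genes lie at 0.88 with FOXO3 and -0.33 with FOXO1.

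The responses to the constructs were then set side by side. Genes called higher in both comparisons numbered 1775 and genes called lower in both 2111, against 529 and 575 for independent lists and means of 0.05 and 0 in 20 simulations of unchanged groups that shared the controls. Those groups held no effects, so their means do not show how much overlap shared controls add to lists of this size. GIMAP4, PRL (4.55 with FOXO3 and 6.27 with FOXO1), TMEM204 (5.02 and 4.46) and the serum protein gene ITIH3 (4.41 and 4.49) were among the largest shared rises. The muscle LIM protein gene CSRP3 (-2.63 and -3.18), RGS1 (-2.20 and -3.23), C6orf223 (-2.10 and -2.29, or -1.49 and -1.66 without control replicate 2) and the receptor TNFRSF13B (-2.05 and -2.34) were among the largest shared falls. HSPA1B also belonged to them (-3.42 and -2.63), although its control libraries overlapped the others and control replicate 1 held 425 CPM against 18.3 and 75.1. Its call with FOXO1 was lost without control replicate 1 (log2 fold change -0.76, adjusted p = 0.248) or FOXO1 replicate 1 (0.0548), 2 (0.0813) or 3 (0.0872), its call with FOXO3 without FOXO3 replicate 3 (0.0511), and both with limma voom and on the deposited normalised values. The call with FOXO1 was also lost in a fit of the 6 compared samples, and the fall with FOXO3 was -1.56 without control replicate 1. Its reads can be split with the near-identical HSPA1A.

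Log2 fold changes of the comparisons correlated across the 18682 tested genes at r = 0.683 and rho = 0.702, where the simulations with shared controls gave means of 0.498 and 0.460. The covariance was 0.357 against a simulated 0.0397, a difference of 0.317. With 3 controls no split into parts of at least 2 was possible, so part of the excess overlap may come from the shared controls. The simulated libraries held no noise shared by FOXO3 and FOXO1 libraries of the same number, which may add to it too. Opposite calls were made for 144 genes, 113 of them higher with FOXO3 and lower with FOXO1 and 31 the reverse. RANBP3L (2.09 with FOXO3 and -2.05 with FOXO1), the pyrimidine enzyme UPB1 (2.18 and -1.65), ALOX5AP, which acts in leukotriene synthesis (1.57 and -1.99), and the transporter ABCA4 (2.07 and -1.51) had the largest opposite changes. IGHV1-69 (1.77 and -2.13) rested on few counts, its FOXO1 and control libraries overlapped, and its call with FOXO3 was lost without control replicate 1 (adjusted p = 0.1) or 2 (0.087) or any FOXO3 library (0.148, 0.0571 and 0.0882). The call with FOXO3 was lost also with both uses of the deposited factors. Without FOXO1 replicate 1 its change with FOXO1 was -3.22, and -4.98 against FOXO3. Its call with FOXO1 was lost without control replicate 2 (0.0694) or 3 (0.166), FOXO3 replicate 3 (0.053) or FOXO1 replicate 2 (0.112) or 3 (0.102).

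**Figure D5:**
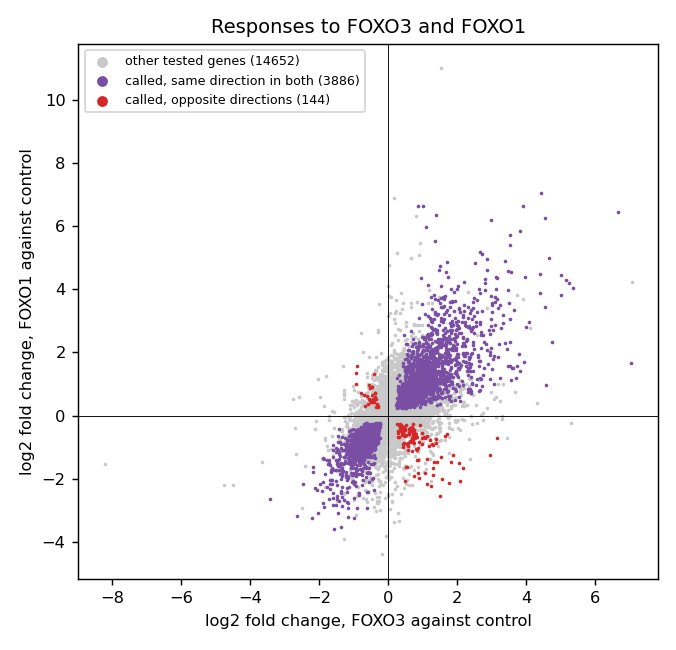
Log2 fold change with FOXO3 (horizontal axis) against that with FOXO1 (vertical axis), both relative to control, 1 point per tested gene, coloured by whether the gene was called in both comparisons and in which directions. The 144 genes called in opposite directions lie in the upper left and lower right.

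The constructs were compared directly in the third comparison. By camera with the preset correlation, the MHC class II, interferon response, ribosomal protein and ribosome biogenesis lists were called lower with FOXO1 than with FOXO3, and TCF3::PBX1-associated genes and progenitor markers higher. With an estimated correlation the lowest adjusted p was 0.101. MT1M was 105-fold higher with FOXO1 (log2 fold change 6.72, SE 0.24, adjusted p = 1.02e-07), CREB3L1 29.8-fold, CCDC91 29.4-fold, the phosphodiesterase PDE11A 20.1-fold, CD247 by 4.17 on the log2 scale, SHISA2 13.9-fold, AHNAK2 12.8-fold, KLF2 9.47-fold, BIK 9.26-fold and the protein kinase A subunit PRKAR2B 9.18-fold. SELENOP was 41.4-fold lower (log2 fold change -5.37, SE 0.17, adjusted p = 2.79e-08), the protease inhibitor A2M 18.4-fold, RANBP3L 17.6-fold, the cytokine IL16 16.7-fold, TMEM140 15.3-fold, the receptor TLR6 14.7-fold, UPB1 14.2-fold and GBP2 12.1-fold, and IGHV1-69 had log2 fold change -3.90, SE 0.71, adjusted p = 0.00357. KIT had 93 counts with FOXO1 against 3 with FOXO3, a ratio of 29.4 with a 95% counting interval of 9.77 to 145.

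Of MHC class II genes, 10 of 11 were lower with FOXO1 than with FOXO3 (10 adjusted over the list alone) (camera adjusted p = 1.57e-11, adjusted p = 0.256 with an estimated correlation). HLA-DOA (log2 fold change -2.06, SE 0.19, adjusted p = 5.78e-05), HLA-DMA (-1.09) and HLA-DPA1 (-1.02) were among them. Of the interferon list, 7 of 20 were lower (8 adjusted over the list alone) (camera adjusted p = 0.000159, adjusted p = 0.101 with an estimated correlation), such as IFIT3 (-2.28) and OAS1 (-1.77). Cytosolic ribosomal proteins had 17 of 26 lower (24 adjusted over the list alone) (camera adjusted p = 2.25e-07, adjusted p = 0.444 with an estimated correlation), such as RPS6 (-0.55) and RPL7 (-0.55). In the MYC and ribosome biogenesis list 5 of 25 were lower (5 adjusted over the list alone), ODC1 most (-1.76) (camera adjusted p = 0.0156, adjusted p = 0.687 with an estimated correlation). The list's call was lost without FOXO1 replicate 3 (adjusted p = 0.0755). Of its members, NPM1 (adjusted p = 0.0542 to 0.064) and PES1 (0.053 to 0.0638) lost their calls when some FOXO3 or FOXO1 library was left out. MYC lost its call without FOXO3 replicate 1 (0.064). Of TCF3::PBX1-associated genes, 4 of 8 were higher, MERTK most (1.69), and 1, WNT16, was lower (-1.16; 5 and 1 adjusted over the list alone) (camera adjusted p = 0.0128, adjusted p = 0.166 with an estimated correlation), a list call lost on the deposited normalised values (adjusted p = 0.106). PBX1, also higher, lost its call without FOXO3 replicate 1 (adjusted p = 0.098), 2 (0.089) or 3 (0.0656) or FOXO1 replicate 2 (0.0912) or 3 (0.0903).

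Other lists were also called in the direct comparison. Mature B and plasma cell markers had 5 of 12 lower (5 adjusted over the list alone), including MS4A1 (-2.18) and CD27 (-1.79) (camera adjusted p = 0.0128, adjusted p = 0.166 with an estimated correlation). TNFRSF13C, also lower, lost its call without FOXO3 replicate 2 (adjusted p = 0.131) or 3 (0.0808) or FOXO1 replicate 1 (0.0988) or 2 (0.094). Of p53 targets, 5 of 21 were lower and 1 higher (5 and 1 adjusted over the list alone), SESN1 among the former (-1.71) (camera adjusted p = 0.0303, adjusted p = 0.166 with an estimated correlation). A minimum mean of 1 CPM ended the call (adjusted p = 0.0516). Progenitor markers had 3 of 6 higher (3 adjusted over the list alone), LMO2 (1.40), KIT and MME, and LYL1 (-0.61, adjusted p = 0.0765) was lower only when adjusted over the list alone (camera adjusted p = 0.0177, adjusted p = 0.166 with an estimated correlation). The call was lost with limma voom (adjusted p = 0.0738), with DESeq2 (0.0784), under both other filters, on the deposited normalised values and in the fit of the 6 libraries with the replicate block (0.0532). The list's median log2 fold change, 0.37, was -0.01 with no filter and -0.06 with DESeq2. T cell markers had 4 of 10 lower and 1 higher (6 and 3 adjusted over the list alone), TRAC (-3.03) and ZAP70 (-1.32) falling below and BCL11B above (camera adjusted p = 0.0434, adjusted p = 0.371 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.0571), 2 (0.0726) or 3 (0.0515), FOXO3 replicate 2 (0.125) or FOXO1 replicate 1 (0.0941) or 3 (0.0693), and with limma voom, limma-trend, a minimum mean of 1 CPM and both fits of 6 samples.

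FOXO target genes were not called between the constructs (3 of 26 higher and 10 lower, 3 and 11 adjusted over the list alone; adjusted p = 0.0644). They were called lower with the replicate number as a block (adjusted p = 0.0272) and without control replicate 1 (0.0363), FOXO3 replicate 1 (0.0394) or FOXO1 replicate 3 (0.0048). DESeq2, limma voom, limma-trend, no filter, the deposited factors as offsets and both fits of 6 samples called the list too. DEPP1 (2.02) was higher with FOXO1 and PIK3IP1 (-2.06) lower. With the block the V(D)J list was also called higher (adjusted p = 0.0371, against 0.0644 without it; RAG1 1.37) and the insulin and PI3K list lower (0.0371, against 0.0644; TSC1 -0.98), the latter called also without FOXO1 replicate 3 (0.0277) and on the deposited normalised values. Both were also called with DESeq2, no filter, the deposited factors as offsets and the block in a fit of the 6 libraries. Oxidative phosphorylation genes were not called (adjusted p = 0.0765) and were called lower without FOXO3 replicate 1 (adjusted p = 0.0435) or FOXO1 replicate 3 (0.0495), and with limma voom (0.0108), DESeq2 (0.0101) and no filter (0.0187). SELL was higher with FOXO1 than with FOXO3 (log2 fold change 2.10, SE 0.14, adjusted p = 8.3e-06), as were CCR7 (1.03) and IRF4 (1.49), while ITGB7 (-2.67), SPIB (-1.93) and PTPRC (-2.75) were lower. By edgeR, 0 of 20 sterol and fatty acid synthesis genes differed between the constructs, with 2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom and limma-trend; LDLR had log2 fold change -0.50, SE 0.16, adjusted p = 0.0539 and passed with the block (adjusted p = 0.00265) and without FOXO3 replicate 1 (0.0355), and FDFT1 (-0.35, adjusted p = 0.12) passed with the block (0.0264). Of 25 G2/M and mitosis genes, 0 differed by any of these tools, and 0 at an unadjusted p under 0.05. In the fit of the 6 libraries with the block, CCNB2 was lower (adjusted p = 0.0452) and BUB1 higher (0.0329).

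Between the constructs other lists held called genes and were not called themselves. Homing genes had 4 of 13 higher and 3 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.0963), and the list was called higher with DESeq2 (adjusted p = 0.0214) and in the fit of the 6 libraries with the block (0.0353). Pre-B receptor signalling genes had 5 of 23 higher and 5 lower (6 and 6 adjusted over the list alone, camera adjusted p = 0.0963), CD22 among the lower (-1.43). B lineage transcription factors had 5 of 25 higher and 4 lower (8 and 5 adjusted over the list alone, camera adjusted p = 0.182), with ERG higher (1.30). DESeq2 called both lists (adjusted p = 0.0162 and 0.043), and the former was also called with no filter (0.0082). For IL7 and cytokine receptors the counts were 3 of 21 higher and 4 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.768), and for S phase genes 2 of 25 higher (2 adjusted over the list alone, camera adjusted p = 0.957). G1 cyclins, CDKs and inhibitors had 4 of 17 higher (4 adjusted over the list alone, camera adjusted p = 0.643). The S phase calls, E2F1 and CCNE2, were lost when some FOXO3 or FOXO1 library was left out. So were the G1 calls, CDK6, CDKN2D, CDKN2A and CDKN1C. CDKN2A lost its call whichever FOXO3 or FOXO1 library was left out (adjusted p = 0.0622 to 0.111). The BCL2 family had 4 of 24 higher and 3 lower (5 and 4 adjusted over the list alone, camera adjusted p = 0.267), its median below 0 (-0.02) while its mean and test pointed up, with HRK higher (0.95) and FAS lower (-1.27). Autophagy and lysosome genes had 5 of 22 lower (5 adjusted over the list alone, camera adjusted p = 0.182) and stress response genes 1 of 20 higher (1 adjusted over the list alone, camera adjusted p = 0.511). NF-kB response genes had 2 of 13 higher and 2 lower (2 and 3 adjusted over the list alone, camera adjusted p = 0.886) and immediate early genes 2 of 17 higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.582). Histones had 3 of 15 lower (3 adjusted over the list alone, camera adjusted p = 0.122), H3C10 most (-1.07), and were called lower with DESeq2 (adjusted p = 0.0364) and no filter (0.0371). The ATG9A, CD40, NFKBIA, MYC, H2AC6 and H2BC9 calls of these lists were also lost when some FOXO3 or FOXO1 library was left out. Adherent cell markers had 1 of 6 higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.744), CDH2 (0.49) and COL1A1 (-0.66), and mitochondrially encoded transcripts had 1 of 15 higher, MT-RNR1 (0.48), and 0 adjusted over the list alone (adjusted p = 0.865). The MT-RNR1 call was lost without FOXO3 replicate 1 (adjusted p = 0.125), 2 (0.0894), 3 (0.0957), FOXO1 replicate 1 (0.0566) or 3 (0.127), and on the deposited normalised values (log2 fold change 0.31 without FOXO1 replicate 3), and those of CDH2 and COL1A1 with both uses of the deposited factors. By edgeR, 0 of 22 glycolysis and hypoxia genes and 0 of 7 myeloid markers differed. At an unadjusted p under 0.05 there were 4 and 2, by DESeq2 0 and 1, by limma voom 0 and 0, and by limma-trend 1 and 0. PFKL passed in the fit of the 6 libraries with the block (adjusted p = 0.0376), GPI without FOXO3 replicate 1 (0.0337), and CSF1R with the block (0.0146), no filter and DESeq2, in both fits of the 6 libraries and without control replicate 1 (0.0378) or FOXO3 replicate 1 (0.0371).

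Of 18682 genes, 3247 differed between FOXO1 and FOXO3, 1445 higher and 1802 lower with FOXO1, 504 and 632 of them past 2-fold. Scaled by library totals alone, 1757 were higher and 1498 lower. Groups did not overlap for 37.2% of genes against 10% by chance. With the preset correlation 9 lists were called, and by fry 17. The MYC and ribosome biogenesis list, called by camera, was not called by fry (adjusted p = 0.0872). The main test left out the assumed pairing of FOXO3 and FOXO1 samples by number. With the replicate block on all samples 4106 genes were called. A fit of the 6 libraries with the replicate block, chosen after seeing the data, called 4939 genes.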

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

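The tests on ribosomal proteins were chosen after that list's change had been seen and before their own values were. Each difference below comes from the direct test of FOXO1 against FOXO3. The MHC class II list had a median log2 fold change of -1.15 between the constructs, having risen with FOXO3 and gone both ways with FOXO1. The interferon list had a median of -0.56 and T cell markers -0.52, which was -0.27 without FOXO3 replicate 2 and -0.33 without FOXO1 replicate 1, with the call lost in both. Mature B and plasma cell markers had a median of -0.34, the MYC and ribosome biogenesis list -0.22 and p53 targets -0.16. Without FOXO1 replicate 3 these medians were -0.60, -0.09 and -0.28, and the ribosome biogenesis call was lost, while without FOXO1 replicate 1 that list had -0.37. TCF3::PBX1 associated genes (0.34) were higher with FOXO1, and progenitor markers had a median of 0.37, which was -0.01 with no filter and -0.06 with DESeq2. With an estimated correlation the lowest adjusted p of the 31 lists was 0.101, and fry called 17. Calls in opposite directions against control were made for 144 genes.

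Cytosolic ribosomal proteins had a median of -0.43 with FOXO1 against FOXO3. Among 10000 random lists matched on transcript length, that median lay at the 0.01 percentile, the smallest they can give. The draws treat genes as independent, although this list's estimated correlation was 0.794, and the list was chosen for its change. The percentile is therefore no measure of significance. The random lists' medians had a median of -0.0293, and the 100 other most abundant protein-coding genes had a median of -0.0226 (SE 0.0529, across genes). These values argue against length bias and against a general loss of reads from abundant genes as the whole cause. The 18 other translation genes had a median of -0.212 (SE 0.0524, across genes), at the 0.64 percentile of lists matched on abundance, also drawn as independent genes, with 3 called lower. A shared change of the translation machinery therefore stays open as a hypothesis, although the value lies close to the bound of -0.2 set for it and is smaller than that of the ribosomal proteins. A difference between the factors themselves, or in how much of each was made, was not tested.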

How the results depend on the processing

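Fits with the deposited factors as offsets, without the unnamed gene, and on 6 samples with the block were chosen after seeing the data. No named gene changed direction past the threshold under any alternative, and no list did by camera's direction. Fry and the estimated correlation were given the main fit's direction, so these settings could not show a change. The median of FOXO target genes with FOXO1 turned from 0.05 to -0.11 without control replicate 1, with the list still called (adjusted p = 0.0346). Of 387 called named-gene results, 337 stayed called under every setting that tested them, 39 lost the call when some library was left out and 29 under some other setting. The rule took most of these genes for large folds or small p in the same data, so that share does not describe all calls. Without control replicate 3, 4117 of 5858 calls with FOXO3 and 5330 of 7046 with FOXO1 were kept. Without FOXO3 replicate 3, 2157 of 3247 between the constructs were kept. Calls ran from 4258 to 6917 for FOXO3 over 21 alternatives, from 5496 to 8007 for FOXO1 over 21, and from 2230 to 4939 between the constructs over 22, the last being the 6 samples with the replicate block. With the block on all samples the counts were 6917, 8007 and 4106, with 4731 genes in both and r = 0.682. Control replicates 1 and 3 were closest to their own number in both other groups, and control replicate 2 in neither. Control replicates 1, 2 and 3 correlated with their own number at 0.224, 0.0611 and 0.0936 (FOXO3) and 0.323, -0.0783 and 0.0718 (FOXO1). With values under 0.1, controls were not taken to pair with the others. For 7 of the 9 libraries the single closest library of another group had the same number. Between the constructs the block on all 9 samples, and the block on the 6 compared, changed no call of a named gene or list other than those printed with the direct comparison.

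Leaving out each library gave 4258 to 6052 calls for FOXO3, 5496 to 6931 for FOXO1, 2230 to 3584 between them, 2703 to 3849 in both and r = 0.654 to 0.706. FOXO3 ranged from 5.21 to 5.33 with its construct and FOXO1 from 1.23 to 1.51. List calls ranged from 16 to 16, 13 to 15 and 8 to 11. The correlation was 0.634 with no filter and 0.568 with DESeq2. Camera with an estimated correlation called 0, 1 and 0 lists (5, 5 and 6 at an unadjusted p under 0.05), and fry called 22 with FOXO1 and 17 between the constructs. Between the constructs 14 lists were called with no filter and 16 with DESeq2. With the deposited factors as offsets the log2 fold change of FOXO1 was 6.05 and of FOXO3 6.67, since those factors differ by library for these genes. The cause of the other shifts was not tested. At 31.6 to 40.5 M counts, ratios of genes with 3 or fewer counts in a group have intervals over 10-fold wide.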

Other observations

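Families below were chosen after their values were seen, as were the tests of FOXO1 reads and the bound by which RNAs without a tail were judged. Of 9 families counted, metallothioneins alone had every member called between the constructs. Among them 6 of 7 rose with FOXO1 (median 2.30) and 7 of 7 were higher than with FOXO3, where 1 fell. No test of the families as sets was run. GIMAP genes rose with both constructs, 3 of 5 with FOXO3 and 5 of 5 with FOXO1 (median 2.88, and 4 rises without control replicate 1). Of guanylate binding proteins, 3 of 5 rose with FOXO3 and 3 of 5 were lower with FOXO1 than with FOXO3. Of heat shock proteins, 9 of 11 fell with FOXO3 and 7 of 11 with FOXO1. Without control replicate 1, which had high HSPA6 and HSPA1A, 9 fell with FOXO3 and 5 with FOXO1. Tubulins, KLF genes, semaphorins and plexins, S100 proteins and apolipoproteins had at most 6 rises and 7 falls each against control.

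Few reads were counted for FOXO1 in the libraries with its construct. The deposited factor of FOXO1, relative to genes with 1 transcript, was at most 0.0499 of its lowest value elsewhere, and that of FOXO3 at most 0.386 in its own libraries. This is the direction that construct reads assigned to short transcripts would give, so it stays open as a hypothesis. ENSG00000288542 held 5.08 times the reads of FOXO1 in those libraries and may be counting construct reads too. Whether its sequence matches FOXO1 cannot be told apart from a gene of its own here, because no sequence of that identifier was used.

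Of replication-dependent histones, 11 of 15 rose with FOXO3 and 10 with FOXO1 (adjusted p = 0.224 and 0.468 with an estimated correlation), while of S phase genes 21 and 19 of 25 fell (adjusted p = 0.359 and 0.468 with an estimated correlation). The summed level of 66 histone genes was 144 ± 27.3 CPM in control, 309 ± 26.3 with FOXO3 and 277 ± 39.1 with FOXO1 (SD, n = 3), ratios of 2.14 and 1.92 with no overlap, which argues against reads moving between near-identical histone genes. For more RNA without a poly(A) tail, 12 other small structured RNAs had medians of 0.0643 (SD 0.491) and 0.114 (SD 0.416), below the log2 histone changes of 1.10 and 0.940 by more than that spread. Under the bound set before the values were seen the same medians did not decide, so that argument is weak. A change in histone transcription, decay or tailing with either factor stays a hypothesis that was not tested.

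Splits of 6 libraries into 3 and 3 number 10, the real one included, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many calls: 5858, 7046 and 3247, against a highest other of 3, 0 and 0 by edgeR. Every other split mixes libraries of both groups, so the difference between the groups adds to the spread within each part. Few calls in those splits, with or without all pairs parted, were likely wherever the groups differ, whatever the cause. No conclusion is drawn from them. At an unadjusted p under 0.05 the other splits reached 1336, 2235 and 1047 genes, and by limma voom 4, 1 and 1 calls. Between the constructs, where the numbers were taken to pair the samples, the 3 other splits that part all 3 pairs gave 0 calls by edgeR and by limma voom.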
